A study of uncultured prokaryote with 4 samples.

How the data were processed

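The labels describe 4 samples, soil and varnish from Cima and from Darwin Pass, 1 array each. Genomic DNA was extracted with a soil DNA kit, and cloned and purified 16S rRNA genes were labelled with Cy3 by random priming with Klenow fragment and hybridised, per the labels' protocols. The series title names pyrosequencing while the labels describe array hybridisation, and the values were treated as array values. Targets were built from consensus sequences of 16S sequence clusters, per the series design text. The unit recorded for the deposited values is signal, 1 value per target and sample, never negative. How probe brightness became 1 value per target, the background correction, the normalization and the rule for zeros are not given in the sources used here. An exact 0 is therefore written as listed at 0, no fold is given against it, and the total signal of a sample need not reflect its DNA.

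The table had 481 rows, of which 478 were 16S targets and 3 were polyphosphate kinase gene rows, which were kept out of all tests. Of the 1912 values of 16S targets, 65.0% were exactly 0. Consensus sequences were 1285 to 1605 bases long (median 1480). Each sample column was matched to its sample by title. Taxon names were used as the table gives them, in the nomenclature of the Ribosomal Database Project, and 104 targets carry a name that starts with unclassified. Each name was placed by hand in a phylum, or in a class for Proteobacteria. No reference sequences were used here to check the names.

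The design, the taxon lists, the rule for named targets and the first set of alternatives were fixed before the data were examined. The plan assumed either counts or intensities, and the branch for intensities was used, with values as deposited. The main fit was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2(signal + 9.8e-05), the pseudocount being the smallest value above 0. Material was fitted with site as a block, and site with material as a block, leaving 1 residual degree of freedom per target, with Benjamini-Hochberg adjustment at 0.05. In the main fit eBayes pooled the variance across targets: between the sites, targets shared a standard error of 4.53 on the log2 scale. The p-values thus borrow their degrees of freedom from targets, which are not independent replicates. The planned filter, above background in at least 1 sample, removed no target. Differences on that scale depend on the pseudocount wherever a sample is listed at 0. The fit was tested on simulated data of 478 targets with a noise SD of 0.3 on the log2 scale, with no zeros and with values under a threshold set to 0.

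Lists were phyla and classes, genera with manganese-oxidising members, desiccation- or radiation-tolerant genera, oxygenic phototrophs, anoxygenic phototrophs, nitrifiers, nitrogen fixers, iron and sulfur cyclers, organelles, and genera of human skin, gut and reagents. In all, 11 lists, among them the last and the iron and sulfur cyclers, had no measured target. The oxygenic phototrophs held the same 28 targets as Cyanobacteria and were given once. Lists of at least 5 targets (14, or 13 distinct) were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. The median varnish minus soil difference of a list was ranked among 10000 random lists of the same size, matched in 10 bins of mean level.

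Within a site there was 1 sample per material and no test, and targets were counted at 2-fold. Similarity was measured by Bray-Curtis dissimilarity of shares of the summed signal, by shared targets and by correlation across targets. Unless stated otherwise, intervals are 95% percentile intervals from 2000 bootstrap draws of taxon names. They cover the choice of taxa and not the spread between samples. Intervals of the area under the curve and of correlations with identity to the brightest target are from draws of single targets. Those treat related targets as independent. The text names, of the targets that differed at least 2-fold in the same direction at both sites, the 10 highest and 10 lowest by mean difference. It also names the 5 and 5 for the sites, the 3 brightest of each sample and members from the 4 of each list with the highest mean signal over the samples. The alternatives were other pseudocounts, scalings, filters and thresholds, no block, an eBayes trend, and presence or absence. Detection thresholds from the polyphosphate kinase rows or at 0.02, scaling to the same total, quantile normalization, sums per taxon name, the estimated correlation and its degrees of freedom, the share of targets above 0 and lists without some of their members were chosen after seeing the data. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, alignments with Biopython 1.88, and figures with matplotlib 3.10.9.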

Results

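Rock varnish is a dark, thin coating that forms on exposed rock surfaces, rich in manganese and iron oxides. The study hybridised labelled 16S rRNA gene material to an array of targets named for bacterial and archaeal taxa. Each target stands for the consensus sequence of 1 cluster of related 16S sequences, and its name gives the taxon, the cluster number and the number of sequences behind it. There were 4 samples, 1 each of Cima soil, Cima varnish, Darwin Pass soil and Darwin Pass varnish. The 2 sites are the only replication of the contrast between materials, so values within a site have no replicate check. The table analysed here held 478 16S targets under 133 taxon names. Every one of them was above 0 in at least 1 sample: 343 targets in 1 sample, 86 in 2, 42 in 3 and 7 in all 4. Targets at 0 in all samples are not in the table, so a count of targets above 0 is not a detection rate of the array. The summed 16S signal was 4.26 in Cima soil, 14.9 in Cima varnish, 16.3 in Darwin Pass soil and 13.2 in Darwin Pass varnish. The median of the values above 0 was 0.0411, 0.0435, 0.0504 and 0.0517 in the same order. The scale of the signal and the rule that set values to 0 are not given in the sources used here, and the number of arrays limits the precision.

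The varnishes and soils of both sites were compared to ask which taxa mark the varnish wherever it was taken. Cyanobacteria, the oxygenic phototrophs of the list, were above 0 in both varnishes and listed at 0 in both soils. Of their 28 targets, 27 were above 0 in Cima varnish and 2 in Darwin Pass varnish, with 12.3% and 3.90% of the signal. Bacteroidetes took 24.1% of the signal of Cima varnish against 12.3% of Cima soil, and 16.2% of Darwin Pass varnish against 9.35% of Darwin Pass soil. At Darwin Pass, of all signal, most of that difference lay in Segetibacter cluster 1: without it the shares were 9.09% and 7.94%. Over the signal left without Acetobacteraceae, a family given below, the difference left without that target would be wider. Bacteroidetes targets above 0 at Darwin Pass were 15 in varnish and 20 in soil, or 11.8% and 8.66% of all targets above 0. Alphaproteobacteria took 28.5% against 16.4% at Cima and 47.9% against 16.7% at Darwin Pass. Of the 47.9%, Acetobacteraceae took 35.9%, and the other Alphaproteobacteria took 12% of all varnish signal, or 18.7% of the signal left without that family, against 16.7% in soil. Crenarchaeota, an archaeal phylum, lay on the soil side: 4 of 7 targets were above 0 in Cima soil and 7 in Darwin Pass soil, with 14.4% and 7.28% of the signal, and all 7 were listed at 0 in both varnishes.

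**Figure D1:**
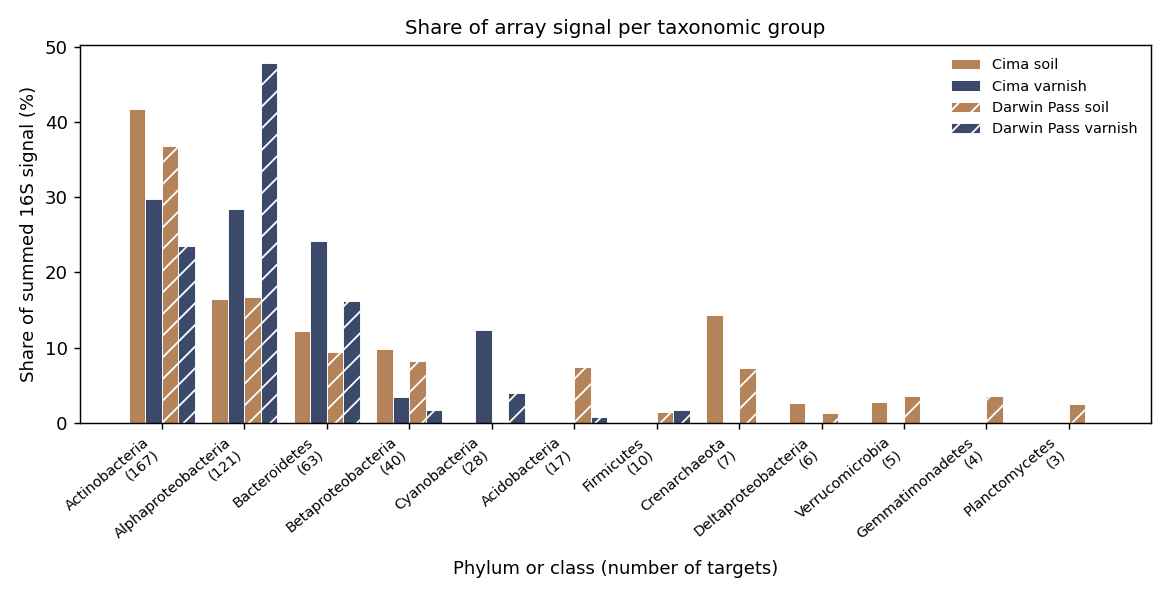
Share of the summed 16S signal of each sample (percent, vertical axis) taken by 12 phyla and classes, with the number of targets of each in parentheses; brown bars are soils, blue bars varnishes, and hatched bars Darwin Pass, with 1 sample per bar and no error. Alphaproteobacteria, Bacteroidetes and Cyanobacteria have the taller bar in varnish at both sites, and Crenarchaeota stand at 14.4% and 7.28% in the soils and at 0 in the varnishes.

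Groups with lower shares in varnish at both sites included Actinobacteria, the group with the most targets. Actinobacteria took 41.8% of the signal of Cima soil against 29.7% of Cima varnish, and 36.9% of Darwin Pass soil against 23.6% of Darwin Pass varnish. Counted as targets above 0, their share at Darwin Pass was on the other side, 42.4% in soil and 46.5% in varnish. Shares are parts of a whole, and Acetobacteraceae alone took 35.9% of the Darwin Pass varnish signal and none of the soil's. That lowers the share of every other group or list in that varnish. Over the signal left without the family, the Actinobacteria share there would lie close to the soil's 36.9%. Their lower share at Darwin Pass thus reflects the signal of that family, which leaves the difference at Cima. Exact shares without the family were worked out for Alphaproteobacteria only. Betaproteobacteria took 9.83% of the signal in Cima soil against 3.39% in Cima varnish, and 8.22% against 1.70% at Darwin Pass. Verrucomicrobia took 2.72% and 3.48% in the soils of Cima and Darwin Pass, and Deltaproteobacteria took 2.61% and 1.28%. Both were listed at 0 in both varnishes. Acidobacteria had 16 of 17 targets above 0 in Darwin Pass soil, with 7.46% of the signal, 1 in Darwin Pass varnish and none at Cima. All 4 Gemmatimonadetes and all 3 Planctomycetes targets were above 0 in Darwin Pass soil and listed at 0 elsewhere, with 3.57% and 2.43% of its signal.

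Tested as lists with limma's camera at a preset correlation, 10 of the 13 distinct lists of at least 5 targets passed an adjusted p of 0.05 between varnish and soil. No list passed once the correlation among its targets was estimated, which also takes the test from 476 degrees of freedom to 1, with an adjusted p of 0.67 for Bacteroidetes and 0.668 for each of the other 7 phyla and classes that had passed. At the preset correlation, Cyanobacteria (28 targets) were higher in varnish with an adjusted p of 6.3e-05, Alphaproteobacteria (121) with 0.00484 and Bacteroidetes (63) with 0.0155. Crenarchaeota were lower with an adjusted p of 6.3e-05, Acidobacteria with 0.00133, Deltaproteobacteria with 0.0141, and Betaproteobacteria and Verrucomicrobia with 0.0158 each. Actinobacteria (167 targets, adjusted p = 0.225) and Firmicutes (10 targets, adjusted p = 0.061) did not pass. The estimated correlation was 0.725 for Cyanobacteria and 0.0476 for Crenarchaeota. Each target has 1 residual in this fit, so the estimate reflects only how far the residuals of a list share a sign. With the estimated correlation and 476 degrees of freedom Crenarchaeota alone passed (adjusted p = 0.000511), and with the preset correlation and 1 degree of freedom 0 lists passed. Resting on so weak an estimate, that result does not set Crenarchaeota apart from the other lists. By fry, which asks whether a list moves one way on balance, the adjusted p was 0.678 for each of the same 8 lists.

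Among random lists of the same size matched on mean level, the median varnish minus soil difference of Cyanobacteria stood at percentile 100 of 10000 lists, that of Bacteroidetes at 100 and that of Alphaproteobacteria at 99.9. Crenarchaeota stood at percentile 0.02, Acidobacteria at 0.19, Deltaproteobacteria at 1.68, Betaproteobacteria at 1.79 and Actinobacteria at 2.21. Firmicutes stood at 3.48 and Planctomycetes at 8.03. These percentiles describe the 4 samples and are not tests across replicates.

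Among fixed lists of function, the 46 targets of desiccation- or radiation-tolerant genera had 31 above 0 in Cima varnish against 6 in Cima soil, and 16 in each of the Darwin Pass samples. They made up 13.3% of all targets above 0 in Cima varnish and 7.69% in Cima soil, and 12.6% in varnish and 6.93% in soil at Darwin Pass. Their share of signal was 12.8% in Cima varnish and 9.25% in Cima soil, and 8.87% in Darwin Pass varnish and 10.2% in Darwin Pass soil (6.61% without Rubrobacter cluster 25). Over the signal left without Acetobacteraceae, which are not in the list, the share at Darwin Pass would be higher in varnish too. The list passed camera with the direction of varnish (adjusted p = 0.0165), with an adjusted p of 0.668 under an estimated correlation. That rested on Hymenobacter, 20 of the 46 targets: without it the adjusted p was 0.658, in the direction of soil, and the share was lower in varnish at both sites, 7.67% against 9.25% at Cima and 4.77% against 10.2% at Darwin Pass. Rubrobacter took 7.67% in soil and 4.19% in varnish at Cima, and 8.48% and 2.15% at Darwin Pass. The list's members with the highest mean over the 4 samples were Rubrobacter clusters 25, 12 and 2 and Blastococcus cluster 2. Rubrobacter cluster 12 was above 0 in all 4 samples, with 0.141 and 0.115 in the soil and varnish of Cima and 0.123 and 0.0922 in those of Darwin Pass. The anoxygenic phototrophs (13 targets), led by Rubellimicrobium, had 11 targets above 0 in Cima varnish and none in Cima soil, and 5 in each Darwin Pass sample (camera adjusted p = 0.0146, and adjusted p = 0.668 with an estimated correlation). Those 5 were 3.94% of all targets above 0 in Darwin Pass varnish and 2.16% in Darwin Pass soil. Rubellimicrobium cluster 3 reached 0.209 in Cima varnish and 0.0865 in Darwin Pass soil.

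The genera with manganese-oxidising members, 43 targets, did not pass between varnish and soil as a list. They had 4 targets above 0 in Cima soil, 11 in Cima varnish, 24 in Darwin Pass soil and 14 in Darwin Pass varnish, with 3.92%, 2.77%, 6.09% and 5.60% of the signal. The adjusted p was 0.385, or 0.694 with an estimated correlation, and the median difference stood at percentile 8.74. Its genera parted. Arthrobacter, 23 of the targets, took 2.44% of the signal in varnish against 1.28% in soil at Cima and 5.60% against 3.40% at Darwin Pass, while Streptomyces, and Bacillus at Darwin Pass, were above 0 in soil and listed at 0 in varnish. Without Arthrobacter the list was lower in varnish (adjusted p = 0.0128, or 0.618 with an estimated correlation). Without Streptomyces its share was higher in varnish at both sites, by 1.499 points at Cima and 0.165 at Darwin Pass, and without Bacillus it was higher by 0.502 at Darwin Pass. No genus of the list belongs to Acetobacteraceae, which took 35.9% of the Darwin Pass varnish signal. Over the signal left without that family, the whole list's share there would be higher than the soil's 6.09%. Arthrobacter cluster 1, the member with the highest mean over the 4 samples, had 0.0978 in Cima varnish, 0.0813 in Darwin Pass soil and 0.0512 in Darwin Pass varnish. It was listed at 0 in Cima soil. Of the nitrifiers, bacteria that oxidise ammonia or nitrite, Nitrospira cluster 19 (0.245) and Nitrosospira cluster 8 (0.0695) were above 0 in Darwin Pass soil and listed at 0 in the other samples. The 4 targets of nitrogen fixers had 1, 3, 3 and 1 above 0 in Cima soil, Cima varnish, Darwin Pass soil and Darwin Pass varnish, with a median difference at percentile 36.9. The 3 chloroplast targets, 1 of Streptophyta and 2 of Bacillariophyta (diatoms), were above 0 in Cima varnish alone, with 0.143, 0.0736 and 0.0724, and their median stood at percentile 93.3. They mark plastids of plants and algae in the sample where the Cyanobacteria targets were most numerous.

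Single targets were then counted by presence against absence. In both varnishes and neither soil, 22 targets were above 0, and in both soils and neither varnish 18 were. Counting targets that differed at least 2-fold in the same direction at both sites, on the log2 scale with a pseudocount, 30 were higher and 23 lower in varnish. By the same count 29 were higher in Cima varnish and Darwin Pass soil than in their partners and 4 in the opposite pair, and 20 were higher and 10 lower at Darwin Pass in both materials. Of the 10 with the highest mean varnish minus soil difference, 5 were Bacteroidetes. Segetibacter cluster 9 had 0.232 in Cima varnish and 0.187 in Darwin Pass varnish, and Adhaeribacter cluster 1 had 0.12 and 0.208. Hymenobacter clusters 43, 49 and 6, of a genus with many pigmented and radiation-tolerant isolates, had 0.0598, 0.0534 and 0.0286 in Cima varnish and 0.0748, 0.0753 and 0.127 in Darwin Pass varnish. Cyanobacteria GpI cluster 48 had 0.0868 and 0.107, and Blastococcus cluster 6 had 0.0565 and 0.139. Sphingomonas cluster 41 had 0.0279 and 0.274, Arthrobacter cluster 60 had 0.0373 and 0.14, and unclassified Frankineae cluster 9 had 0.0814 and 0.0517. All 10 were listed at 0 in both soils, which the ranking itself favours: with so small a pseudocount, a value set against 0 gives the largest differences.

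The 10 with the lowest mean difference were all listed at 0 in both varnishes, which the ranking favours in the same way. Unclassified Thermoprotei cluster 36, an archaeal target, had 0.387 in Cima soil and 0.14 in Darwin Pass soil, and unclassified Thermoprotei cluster 115 had 0.153 and 0.049. Rubrobacter cluster 14 had 0.186 and 0.068, and Sphingomonas cluster 132 had 0.0836 and 0.147. Unclassified Bacteroidetes cluster 12 had 0.097 and 0.115, Ferruginibacter cluster 7 had 0.0635 and 0.0727, and unclassified Chitinophagaceae cluster 8 had 0.0663 and 0.06. Unclassified Nannocystineae cluster 12, of the Deltaproteobacteria, had 0.111 and 0.0661. Unclassified Geodermatophilaceae cluster 3 had 0.0363 and 0.0951, and Conexibacter cluster 38 had 0.0695 and 0.0453. Sphingomonas and the Bacteroidetes thus had targets on both sides.

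**Figure D2:**
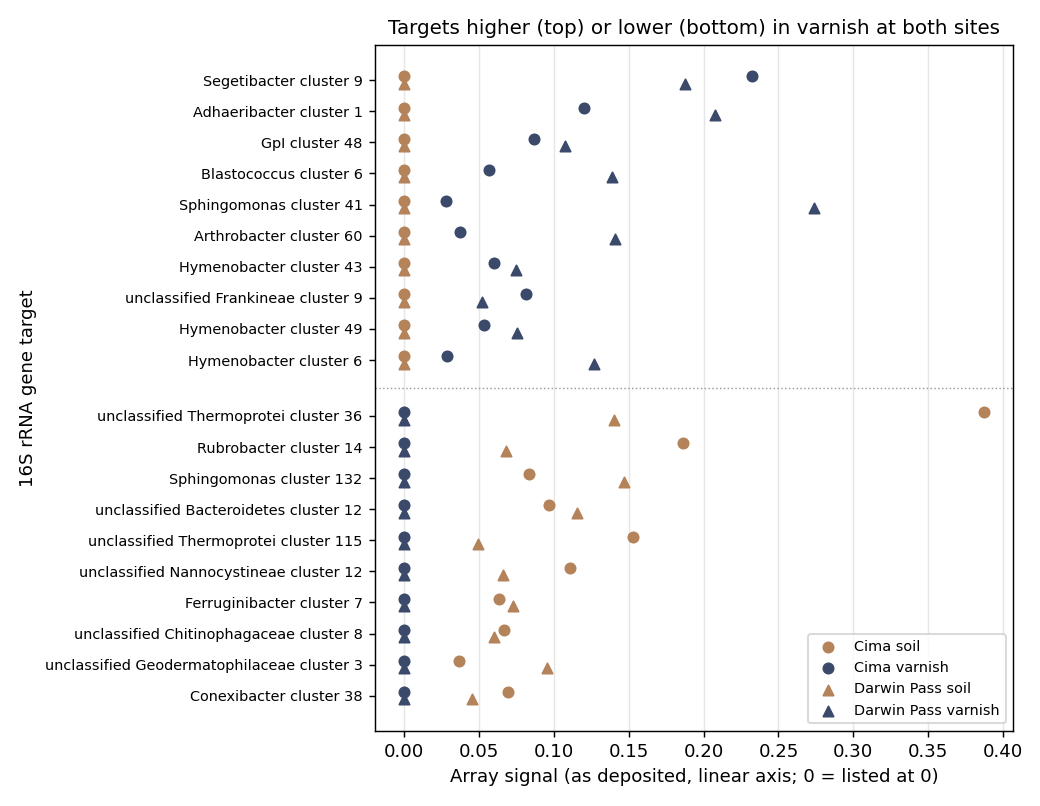
Array signal (linear horizontal axis, as deposited) of the 10 targets with the highest and the 10 with the lowest mean varnish minus soil difference among those that differed at least 2-fold in the same direction at both sites; circles are Cima, triangles Darwin Pass, brown soil and blue varnish, 1 value per sample. The upper 10 are listed at 0 in both soils and the lower 10 in both varnishes, and unclassified Thermoprotei cluster 36 reaches 0.387 in Cima soil. A ranking with a small pseudocount favours targets listed at 0 on 1 side.

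No single target passed the test between materials. With limma on log2(signal + 9.8e-05) and site as a block, 0 of 478 targets had an adjusted p under 0.05. The smallest adjusted p was 0.564, and 23 targets had an unadjusted p under 0.05, 11 higher and 12 lower in varnish. With the variance pooled across targets, the unadjusted p follows the size of the difference alone. On simulated values without zeros the same fit called 74% of targets with a log2 difference of 1 and 100% of those with 2 or more. With as many zeros as the table has, set by a threshold on the simulated values, it called 2% at 1, 8% at 2 and 14% at 4 and at 6. The simulated noise had an SD of 0.3 on the log2 scale, while the fit to the data gave a standard error of 4.53. The simulated rates, with or without zeros, therefore do not give the power of the test on these data.

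Taxon names were then followed as groups, chosen for description after their values were seen. Hymenobacter had 18 of 20 targets above 0 in Cima varnish and 8 in Darwin Pass varnish, and was listed at 0 in both soils. Cyanobacteria GpI had 18 of 19 above 0 in Cima varnish and 2 in Darwin Pass varnish, and Adhaeribacter had 6 of 6 and 1. With Actinomycetospora and unclassified Microbacteriaceae these made the 5 names above 0 in both varnishes and neither soil. The opposite pattern held for 9 names: unclassified Thermoprotei, Streptomyces, Ferruginibacter, Spartobacteria, unclassified Chitinophagaceae, unclassified Bacteroidetes, unclassified Actinobacteria, unclassified Rubrobacteridae and unclassified Nannocystineae. Streptomyces, filamentous spore-forming soil bacteria, had 3 of 5 targets above 0 in each soil. Sphingomonas, with 42 targets, was above 0 in every sample, with 13, 25, 15 and 14 targets in Cima soil, Cima varnish, Darwin Pass soil and Darwin Pass varnish.

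**Figure D3:**
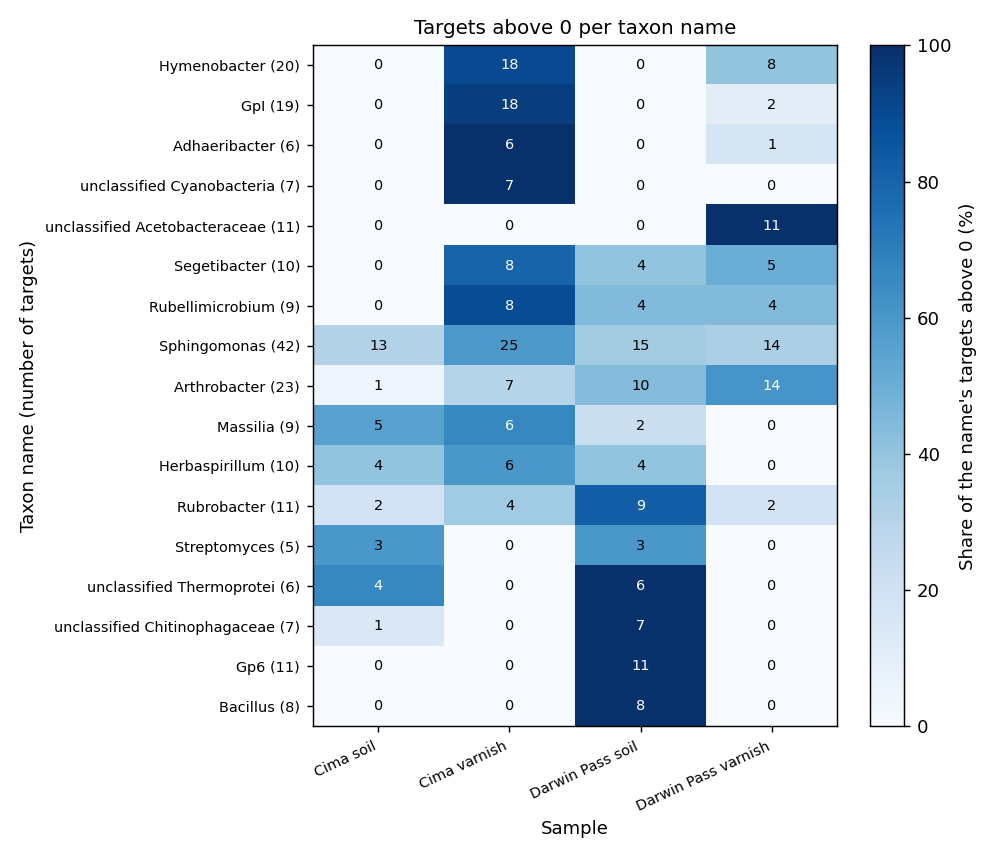
Number of targets above 0 (printed in each cell) for 17 taxon names in the 4 samples, shaded by the percent of the name's targets, with the number of targets of the name in parentheses on the vertical axis. Hymenobacter has 18 and 8 targets above 0 in the varnishes and none in the soils, and the 11 targets of unclassified Acetobacteraceae are all above 0 in Darwin Pass varnish.

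At Cima, the varnish carried more of the array's targets than the soil. In varnish 233 targets were above 0 and in soil 78, with 28 in both, 205 in varnish alone and 50 in soil alone. Of the 28 targets above 0 in both, 3 were at least 2-fold higher in varnish and 8 at least 2-fold lower. The brightest targets of Cima soil were unclassified Thermoprotei cluster 36 (0.387), Flavisolibacter cluster 1 (0.2) and Rubrobacter cluster 14 (0.186). Those of Cima varnish were Sphingomonas cluster 212 (0.386), Cyanobacteria GpI cluster 45 (0.383) and Segetibacter cluster 1 (0.332). The Cytophagaceae, the Bacteroidetes family of Hymenobacter and Adhaeribacter, had 26 of 29 targets above 0 in Cima varnish and none in Cima soil. The Shannon index was 5.0 in varnish and 4.01 in soil. At a threshold set by the polyphosphate kinase rows of each sample the count turned, with 49 targets in soil and 33 in varnish, and so did the Shannon index (varnish minus soil -0.26).

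At Darwin Pass, the soil carried more targets than the varnish. In soil 231 targets were above 0 and in varnish 127, with 46 in both, 185 in soil alone and 81 in varnish alone. Above the highest polyphosphate kinase value of any sample there were 18 in each, and above that of each sample 30 in soil and 18 in varnish. Of the 46 in both, 13 were at least 2-fold higher in varnish and 9 at least 2-fold lower. The soil's brightest targets were Rubrobacter cluster 25 (0.58), unclassified Thermoprotei cluster 237 (0.43) and unclassified Desulfurococcales cluster 3 (0.423). The varnish's brightest were unclassified Acetobacteraceae cluster 39 (1.04), unclassified Acetobacteraceae cluster 5 (1.02) and Segetibacter cluster 1 (0.94). These 3 took 22.7% of the varnish signal. Acetobacteraceae as a family, which includes acetic acid bacteria, took 35.9% of the signal of Darwin Pass varnish, 0.974% of that of Cima varnish and 0% of that of either soil. Bacillus, which forms endospores, had 8 of 8 targets above 0 in Darwin Pass soil, and Acidobacteria Gp6 had 11 of 11. Firmicutes signal in Darwin Pass varnish came from Planococcus cluster 5 (0.222). The Shannon index was 4.09 in varnish and 5.01 in soil.

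The differences of the 2 sites were set against each other to see how far the same targets separated varnish from soil. Of the 117 targets that differed at both sites, 72 had the same sign, 42 higher and 30 lower in varnish at both. Independent signs with the same numbers of higher and lower targets would give 55.0. A further 38 were higher in varnish at Cima and lower at Darwin Pass, and 7 the reverse. Across all 478 targets, which are not independent replicates, the 2 differences had a Pearson r of 0.202 (95% bootstrap interval over taxon names 0.092 to 0.325) and a Spearman rho of 0.234 (0.119 to 0.356). With only values above the highest polyphosphate kinase value of each sample kept, Pearson's r was 0.0745.

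Between the sites, Acidobacteria and Cyanobacteria passed camera at the preset correlation. Acidobacteria were higher at Darwin Pass with a camera adjusted p of 0.0013 and Cyanobacteria lower with 1.66e-06, both with an adjusted p of 0.794 under an estimated correlation. Each call lay mostly in a single array: 16 of 17 Acidobacteria targets were above 0 in Darwin Pass soil and 27 of 28 Cyanobacteria targets in Cima varnish. The same arrays gave the differences of these lists between varnish and soil. For these lists a difference between sites and a difference between materials cannot be told apart. In soil 39 targets were above 0 at both sites, 192 at Darwin Pass alone and 39 at Cima alone. In varnish 57 were above 0 at both sites, 176 at Cima alone and 70 at Darwin Pass alone. Targets above 0 in both Darwin Pass samples and listed at 0 at Cima numbered 11. The 5 with the highest mean difference were Methylibium cluster 11 (0.0794 in soil, 0.0774 in varnish), unclassified Micrococcineae cluster 1 (0.0493, 0.0849), Pseudonocardia cluster 32 (0.0763, 0.0351) and Arthrobacter clusters 67 (0.0666, 0.0264) and 87 (0.0208, 0.071). Targets above 0 in both Cima samples and listed at 0 at Darwin Pass numbered 7. Massilia cluster 10 had 0.0715 in soil and 0.0331 in varnish, Flavisolibacter cluster 2 had 0.0485 and 0.0344, and Pseudosporangium cluster 1 had 0.0539 and 0.028. Sphingomonas cluster 61 had 0.0119 and 0.059, and unclassified Oxalobacteraceae cluster 9 had 0.0271 and 0.0191. The Oxalobacteraceae, the family of Massilia and Herbaspirillum, had 10, 13 and 7 of 21 targets above 0 in Cima soil, Cima varnish and Darwin Pass soil, and none in Darwin Pass varnish. No single target passed limma between sites with material as a block: 0 of 478 were called, the smallest adjusted p was 0.617, and 4 had an unadjusted p under 0.05.

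On average, samples of the same material lay closer than samples of the same site. The Bray-Curtis dissimilarity of signal shares was 0.846 between the soils and 0.808 between the varnishes. It was 0.924 between soil and varnish at Cima and 0.877 at Darwin Pass. The lowest of the 6 pairs was Cima varnish with Darwin Pass soil (0.78), the pair with the most targets above 0, and the highest was Cima soil with Darwin Pass varnish (0.944). The mean of same-site pairs exceeded that of same-material pairs by 0.0733 (95% bootstrap interval over taxon names 0.0361 to 0.108). Pairs that share neither site nor material had a mean of 0.862, below the 0.900 of same-site pairs. Pearson correlations of log2 signal across targets were 0.059 between the soils and -0.026 between the varnishes, and -0.114 and -0.157 between soil and varnish at Cima and Darwin Pass. The product of shared targets over same-material pairs (39 and 57) was 1.73 times that over same-site pairs (28 and 46), with an interval of 1.17 to 2.90. That ratio would be 1 if sharing followed only the number of targets in each sample. The 4 samples can be split 2 against 2 in 3 ways. Without a block limma called 0 targets for each, with 36 at an unadjusted p under 0.05 for material, 2 for site and 17 for the crossed split.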

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

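Of the tests in this part, those of the polyphosphate kinase rows, of weak signals at Cima alone, of arrays dimmed on purpose and of a list without some of its members were chosen after the results were seen.

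The number of targets above 0 went opposite ways at the 2 sites: varnish minus soil was 155 targets at Cima and -104 at Darwin Pass, and with 1 sample per group the difference was not tested. A dim array would keep the brighter targets of its partner. The area under the curve was 0.545 for Cima soil in Darwin Pass soil (95% bootstrap interval over targets 0.454 to 0.641) and 0.52 for Darwin Pass varnish in Cima varnish (0.439 to 0.599). Other arrays dimmed on purpose to their brightest targets had 0.666 and 0.681 in Darwin Pass soil, above the value of Cima soil, and 0.504 and 0.672 in Cima varnish. The measure does not decide, since all of these lie under the 0.7 set for a dim array. Those in Darwin Pass soil rest on 27 and 14 shared targets, and Darwin Pass soil, with 231 targets, had 0.729 in Cima soil. The polyphosphate kinase rows of Cima soil, 0.0255 to 0.0339 against 0.0549 to 0.125 in Cima varnish, were lower in soil, as a dim array would show. Weak signals near the background stay open: above the highest polyphosphate kinase value of any sample, 85.7% of the targets at Cima lay on varnish (18 against 3, exact binomial interval 63.7% to 97.0%), but above each sample's own value soil had 49 and varnish 33, and at Darwin Pass the share was 50% (18 against 18, interval 32.9% to 67.1%), an interval that also holds the 35.5% seen without a threshold. Dim arrays and weak signals cannot be told apart from a difference between the communities of the sites, which was not tested.

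The polyphosphate kinase gene, which makes polyphosphate, had 3 rows that carried signal although the labels describe 16S rRNA gene material. Their highest values were 0.0761 for clone DUR_B10 in Darwin Pass soil, 0.175 for DUR_H10 in Darwin Pass varnish and 0.0999 for NS_D3 in Darwin Pass soil, and 11 of their 12 values were above 0. A uniform background added to every row stays open: 65.0% of 16S values are exactly 0, but the rule that sets values to 0 is not given. Hybridisation specific to these rows, from DNA that resembles them, cannot be told apart from other sources, because at least 2 of the 3 rows were above 0 in every sample and no sample lacked them. In Cima soil 62.8% of the 16S targets above 0 exceeded the brightest of these rows, against 14.2% in Cima varnish, 13.0% in Darwin Pass soil and 14.2% in Darwin Pass varnish.

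Desiccation- or radiation-tolerant genera had opposite differences in share of signal at the sites, 3.51 percentage points at Cima and -1.29 at Darwin Pass, varnish minus soil. The difference was not tested. The sign at Darwin Pass turned without the 3 brightest targets of each sample (7.82 at Cima and 4.23 at Darwin Pass) and by share of targets above 0 (5.61 and 5.67). Which genera are counted changes the sign at each site: without Hymenobacter the differences were -1.58 and -5.39 points, and without Rubrobacter 7.001 and 5.04. Signal outside the list matters too. Acetobacteraceae took 35.9% of the Darwin Pass varnish signal and none of the soil's, which lowers the list's share in that varnish. No genus of the list belongs to that family. Over the signal left without it, the list's share at Darwin Pass would be higher in varnish than in soil, as at Cima. Without Rubrobacter cluster 25 alone, the brightest target of Darwin Pass soil, the list took 6.61% of all signal there and 8.87% in the varnish.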

How the results depend on the processing

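Settings that use 0.02, the polyphosphate kinase rows, sums per taxon name, the share of targets above 0, the estimated correlation or lists without some of their members were chosen after seeing the data. The count of single targets called by limma was 0 between materials and between sites under all 9 alternatives each, with the smallest adjusted p between 0.0745 and 0.634 for material and between 0.0502 and 0.758 for site. The lists called between varnish and soil went from 10 to 0 with an estimated correlation and to 0 with fry, and those between the sites from 2 to 0. The estimated correlation comes with 1 degree of freedom in place of 476: the correlation alone left 1 list and 0, and the degree of freedom alone left 0 and 0. Pseudocounts, scaling to the same median or total and a 4-fold threshold left every count and correlation across sites within the margins set for them. The stricter filter left 7 targets, so that 0 were higher and 2 lower in varnish at Cima, 1 higher and 1 lower at Darwin Pass, and the sites' differences had r = 0.815, rho = 0.75 and 71.4% of signs alike. With values of 0.02 or less set to 0, rho was 0.171, and the product of shared targets over same-material pairs was 2.61 times that over same-site pairs. With values up to the highest polyphosphate kinase value of the sample set to 0, 33 targets were higher in varnish at Cima, 18 were higher and 29 lower at Darwin Pass, r was 0.0745, rho 0.0897, and 80% of 10 signs were alike. Under that threshold the varnish minus soil count reversed at Cima (-16) and was -12 at Darwin Pass, and the Shannon difference reversed at Cima (-0.26) and was -0.637 at Darwin Pass. That threshold lies at 0.0339 in Cima soil and at 0.125 in Cima varnish. At the highest value of any sample the counts were 15 and 0. Summed per taxon name, r was 0.371 and rho 0.399. Of the lists, 4 had a higher and 7 a lower share of signal in varnish at both sites. In Darwin Pass varnish every share outside Acetobacteraceae is lowered by the 35.9% of signal that this family took. Over the signal left, the manganese and desiccation lists would have a higher share there than in soil, and Actinobacteria a similar one. By median log2 difference 0 lists were higher and 1 lower in varnish at both sites. The lower lists were 4 by share of targets above 0 and 4 at the polyphosphate kinase threshold of the sample. The varnish minus soil difference of single lists changed sign at Darwin Pass by share of targets above 0 for Actinobacteria (4.03 points), Firmicutes (-3.11), the manganese list (0.634) and the desiccation list (5.67). Without the 3 brightest targets of each sample it did so for the manganese (0.563) and desiccation lists (4.23), and by median log2 difference for Firmicutes (-6.69). At Darwin Pass, without Rubrobacter cluster 25 the desiccation list had 2.27 points of all signal and 2.02 of the signal left. Without Acetobacteraceae, Alphaproteobacteria had -4.71 points of all signal there, but of the signal left they took 18.7% in varnish and 16.7% in soil. Without 1 genus at a time, the desiccation list had -1.58 points at Cima without Hymenobacter (camera adjusted p = 0.658, now in the direction of soil) and 5.04 at Darwin Pass without Rubrobacter, and the manganese list had 1.499 at Cima and 0.165 at Darwin Pass without Streptomyces and 0.502 there without Bacillus. Nitrogen fixers changed sign at Cima without Balneimonas (0.196), by median (4.11), by targets above 0 (0.0055) and at the polyphosphate kinase threshold (0.842). Except where stated, the cause was not tested. The planned filter and its absence are the same, since no target is removed, and a detection threshold 2 times higher was not run, since the threshold is 0. The count model planned for count tables was not run. Shared targets at the polyphosphate kinase threshold gave no ratio, since a pair of samples shared none. Signal over background is unknown and limits every count.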

Other observations

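Of the tests in this part, the reshuffling of detection profiles was chosen after the result was seen, and so were the relations of signal to the properties of the consensus sequences.

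Only 11 taxon names were above 0 in all 4 samples: Actinoplanes, Arthrobacter, Balneimonas, Blastococcus, Micromonospora, Pseudonocardia, Rhodoplanes, Rubrobacter, Sphingomonas, unclassified Geodermatophilaceae and unclassified Rhizobiales. Most of these are Actinobacteria. Arthrobacter had 1, 7, 10 and 14 of 23 targets above 0 in Cima soil, Cima varnish, Darwin Pass soil and Darwin Pass varnish, and Rubrobacter had 2, 4, 9 and 2 of 11. Below the level of the family, names parted company: Chitinophagaceae took between 7.97% and 13.2% of the signal in each sample, while within it Segetibacter had 0, 8, 4 and 5 of 10 targets above 0 and unclassified Chitinophagaceae had 1, 0, 7 and 0 of 7. Segetibacter cluster 1 was among the 3 brightest of both varnishes (0.332 and 0.94), had 0.23 in Darwin Pass soil and was listed at 0 in Cima soil.

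The pair of samples that shares neither site nor material, Cima varnish and Darwin Pass soil, had 24 targets above 0 in both and in no other sample, against 4 for Cima soil and Darwin Pass varnish. They are the 2 samples with the most targets above 0 (233 and 231). Allowing for those numbers, the crossed pairs shared less than same-material pairs: the product of shared targets over same-material pairs was 2.41 times that over crossed pairs (95% bootstrap interval 1.48 to 5.82). Over same-site pairs it was 1.40 times (0.900 to 2.85), an interval that holds 1. By mean Bray-Curtis dissimilarity the crossed pairs were closer (0.862) than same-site pairs (0.900). Sphingomonas cluster 212 had 0.386 and 0.356 in them. The names above 0 in that pair alone numbered 8, among them Microvirga, Nocardioides, Solirubrobacter and Cryobacterium, and no name was above 0 in the opposite pair alone. Among the targets that a pair of samples shared, whatever the other samples showed, Spearman correlations of signal ranged from 0.319 (the soils, 39 targets) to 0.819 (Cima soil and Darwin Pass varnish, 13 targets).

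All targets of some taxon names were above 0 in 1 sample only. Of 31 names with at least 5 targets, 5 were so: Bacillus, Acidobacteria Gp6 and unclassified Deltaproteobacteria in Darwin Pass soil, unclassified Cyanobacteria in Cima varnish and unclassified Acetobacteraceae in Darwin Pass varnish. Placement without regard to the name is argued against, since 0% of 10000 reshuffles of the profiles among targets gave as many, and the highest gave 2. Targets of a name are related sequences and not independent, so the test shows only that they tend to share a profile. One bright sequence binding related targets could also give such a block, and stays open: the signal of the other 10 unclassified Acetobacteraceae targets had a Spearman correlation of 0.418 with their identity to the brightest (95% bootstrap interval over targets -0.275 to 0.698, identities 92.9% to 99.5%). For the other 17 Cyanobacteria GpI targets of Cima varnish, a name also above 0 in Darwin Pass varnish, it was -0.0172 (-0.561 to 0.539), and neither interval decides.

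Among targets above 0, those whose consensus held more ambiguous bases had lower signal. Across targets, which are not independent replicates, Spearman's rho was -0.329 in Cima varnish, -0.206 in Darwin Pass soil and -0.414 in Darwin Pass varnish. The permutation p was 1e-05 (the smallest the permutations can give), 0.00169 and 1e-05, with adjusted p of 8e-05, 0.00541 and 8e-05 over 16 relations. In Cima soil rho was -0.215 (permutation p = 0.0595, adjusted p = 0.106). Signal was also lower for clusters of more sequences, with rho of -0.249, -0.159 and -0.287 in Cima varnish, Darwin Pass soil and Darwin Pass varnish (permutation p = 8e-05, 0.0161 and 0.00094; adjusted p = 0.000427, 0.043 and 0.00376). With consensus length rho was -0.154, -0.135, -0.0897 and -0.195 in Cima soil, Cima varnish, Darwin Pass soil and Darwin Pass varnish (permutation p = 0.176, 0.0394, 0.174 and 0.0279; adjusted p = 0.249, 0.0787, 0.249 and 0.0637). With cluster size in Cima soil rho was -0.151 (adjusted p = 0.249). With GC content rho lay between -0.0509 and 0.022, with adjusted p of 0.65 or more in every sample.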
